A study of Mus musculus with 48 samples.

How the data were processed

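The series holds 48 mouse samples, of which 30 RNA-sequencing libraries were used. The other 18 samples are chromatin immunoprecipitation libraries and were not analysed here. Per the labels' protocols, RNA was extracted from sorted or cultured cells, polyadenylated RNA was selected, and strand-specific single-end libraries were made. Per the submitters' processing notes, the tools were TopHat 1.4.1, HTSeq 0.5.3 and DESeq 1.8.3 with the mm9 genome. What each tool did, and any filter, is not given in the sources used here.

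The deposited values are RPKM, reads per kilobase of gene model and M mapped reads, as the authors computed them for each library. They cover 21025 gene models named by symbol and RefSeq accession. Of these, 20662 were matched to a current symbol by accession, and 109 share a symbol with another model. No raw counts were used, and no count test was run.

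RPKM values of short, low genes fell on whole multiples of the value of 1 read, which gave an implied number of reads per library. All values used for this were whole within a tolerance of 0.1 read. In 4 libraries there were values of 2 step sizes, and the implied depth of those is an average. The implied depth ranged from 2.3 to 36.2 M (mega, the SI prefix) reads. The implied depths are estimates and were used only to describe the libraries.

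Groups came from the labels alone. The pro-B and pre-B libraries make 14 libraries in 7 groups of 2. The knock-down libraries make 16 libraries in 4 groups of 4. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. None of the 435 pairs of libraries held identical values. Pearson's r of log2 values between libraries of a group ran from 0.964 to 0.992, across genes, which are not independent replicates.

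Differences were tested with limma 3.58.1 in R 4.3.3, on log2(RPKM + 1), with an intensity trend and robust variance moderation. Fold changes are therefore on the log2(RPKM + 1) scale, which understates the change of low genes. A gene entered a fit with an RPKM of at least 1 in at least 2 of its libraries. That left 11937 genes in the pro-B and pre-B fit, with 7 residual degrees of freedom, and 10744 in the knock-down fit, with 12. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p below is from limma unless a gene list is named. Differences between the deletion effects were tested as interactions in the same fit. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, and matplotlib 3.10.9 drew the plots.

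There were 20 gene lists, fixed before the data were examined, as were the groups, tests, thresholds, gene naming rule and most alternatives. They cover the Ikaros family, NuRD and PRC2 subunits, the pre-BCR and its signalling, B-lineage identity, pre-B and later B genes, integrins and focal adhesion, chemokine receptors and migration, Notch targets, T-lineage, myeloid, erythroid and megakaryocyte, NK and dendritic cell, and plasma cell markers, stem and progenitor genes, IL-7 receptor and STAT5 targets, the mitotic cell cycle, DNA replication, glycolysis, interferon-stimulated genes, and immediate early and stress genes. Lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation. Calls within a list were also counted when adjusted over the list alone. The median, the mean and the test of a list differed in sign in 20 of 100 list tests, none of them a called list. Of the 21 calls, 2 hold with an estimated correlation. A second granulocyte list and a second list of monocyte and macrophage genes were written later, for tests of explanations.

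Genes were named by a rule. In each of 5 main comparisons it takes Ikzf1, up to 10 called genes each way with the largest fold, a mean of at least 3 RPKM in the higher group and no overlap between libraries, and up to 3 called members of each list. Predicted, microRNA and small nucleolar genes were left out. For differences of effect it takes up to 5 genes each way, and for genes shared by the 3 deletions up to 10 each way. The text gives some of the genes that the rule took, picked for what is known of them. Genes outside the rule are said to be so. One gene that the rule took is not reported here.

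In the knock-down libraries the 4 replicates of each construct fall into 4 runs of consecutive library numbers. Deviations from the group means were compared across genes. All 24 same-run pairs correlated, with a lowest r of 0.52 and a median of 0.775, against a median of -0.236 between runs. Each of the 16 libraries correlated best with one of its own run. The replicate numbers therefore pair these libraries, although the labels state no shared day. The fit as designed has no block, and the numbers of called genes and called list members from a fit with the run as a block are given beside it.

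The pipeline was tested on simulated data. In a simulation of the pro-B deletion over 11937 genes, 25.4% of genes changed by 1.5-fold, 70.1% changed by 2-fold and 95.5% changed by 4-fold were called, and 6 of 133 calls were false. The same shares were 22.4%, 68.7% and 92.4% for the c-Kit-high deletion, with 8 of 130 calls false. For the Rag2-null deletion they were 25.4%, 61.2% and 90.9%, with 8 of 126 false. For the pre-B comparison they were 35.8%, 67.2% and 95.5%, with 5 of 137 false. Over 10744 genes, they were 76.1%, 92.5% and 100.0% for the knock-down, with 8 of 187 false. With the block they were 70.1%, 85.1% and 100.0%, with 9 of 179 false. For Ik4056 against Ren713 they were 34.3%, 80.6% and 93.9%, with 6 of 145 false. The simulated libraries without the block had no run differences, unlike the real ones, so their false calls do not check that fit against runs. The simulation with the block added run differences to a spread that already held them. These shares therefore do not compare the power of the fits with and without the block. A simulated shift of the glycolysis list by -1 on the log2 scale over 11937 genes was recovered with a camera adjusted p of 7.5e-48. Of the 19 other lists, 0 were called by camera. In the real pro-B and pre-B fit, the estimated correlation within a list ran from -0.096 (Ikaros family) to 0.475 (mitotic genes). It was 0.155 for glycolysis. The simulation did not model such correlation, so its 0 other calls do not check false calls of lists of correlated genes.

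Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 3 RPKM, quantile and median-ratio scaling, limma without trend and robust moderation, an added 2-fold minimum, an adjusted p under 0.1, all 30 libraries in a single fit, only the libraries compared, each control construct alone, the block, another pro-B control or deletion for the stage comparisons, and each replicate left out. Other splits of the samples were fitted for comparisons of groups of 4.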

Results

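Ikaros, the zinc finger transcription factor encoded by Ikzf1, is needed for B-lineage development. RNA was sequenced from mouse cells at successive early B-cell stages with Ikzf1 deleted or knocked down. Pro-B cells came from mice whose controls were Ikzf1(fl/+) Cd79a(Cre/+) and whose deleted counterparts were Ikzf1(fl/-) Cd79a(Cre/+); the Cre recombinase is expressed from a B-lineage gene. The settings were pro-B cells, c-Kit-high pro-B cells and Rag2(-/-) pro-B cells, with 2 control and 2 deleted libraries each. There were also 2 libraries of wild-type pre-B cells. Pre-pro-B cells in culture carried an empty vector, a Ren713 control hairpin, or the Ikzf1 hairpins Ik4056 or Ik2709, with 4 libraries each. The implied depth was 10.2 to 12.4 M reads for the pro-B libraries, 26.9 to 33.9 M for the Rag2-null libraries, 8.7 and 15.5 M for pre-B, and 17.1 to 36.2 M for the knock-down libraries. Of the c-Kit-high libraries, the deleted pair had 9.2 and 9.4 M and the controls 8.8 and 2.3 M.

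Ikzf1 RNA in every library was the first value examined. In pro-B cells it was 59.2 and 56.4 RPKM in the controls and 45.3 and 48.9 in the deleted libraries, a log2 difference of -0.29 ± 0.14 (SE) that was not called (limma adjusted p = 0.178), except with the compared libraries alone in the fit. In c-Kit-high cells it was 101.3 and 123.8 RPKM in the controls and 64.5 and 86.0 after deletion (log2 -0.58, adjusted p = 0.0144). That call was lost without the deleted replicate 1 (log2 -0.38), without the control replicate 2 (log2 -0.44), with all 30 libraries in a single fit and with the compared libraries alone. In Rag2-null cells it was 62.3 and 56.2 RPKM against 39.9 and 36.7 (log2 -0.62, adjusted p = 0.00893), a call lost without the deleted replicate 2 (log2 -0.56) and with all 30 libraries in a single fit. A value over the whole gene model cannot resolve a deleted exon, so these levels check the deletion labels little. Wild-type pre-B libraries held 343.5 and 308.8 RPKM. With hairpins the level was a direct check: empty-vector libraries held 145.3, 110.0, 111.9 and 138.5 RPKM and Ren713 libraries 141.0, 106.1, 110.5 and 136.2, against 53.2, 23.7, 31.2 and 51.5 with Ik4056 and 51.8, 30.8, 40.8 and 60.6 with Ik2709. The knock-down fell by 1.57 ± 0.17 (SE) on the log2 scale, with an adjusted p of 6.54e-06.

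**Figure D1:**
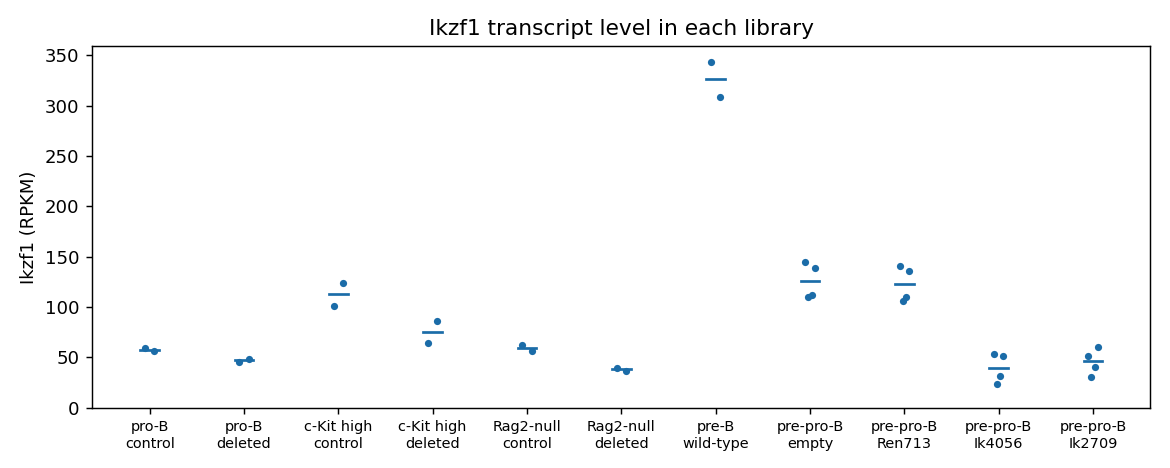
Ikzf1 RPKM in each of the 30 RNA libraries, by group; dots are libraries and bars group means. All 8 libraries with an Ikzf1 hairpin lie at or below 60.6 RPKM, and all 8 control-vector libraries at or above 106.1.

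Loss of Ikaros in pro-B cells was compared with its control to ask which genes depend on it once B-lineage commitment has begun. Enzymes of glycolysis fell together: 13 of 20 tested members fell and 0 rose (14 when adjusted over the list alone; camera adjusted p = 1.68e-07, but adjusted p = 0.316 with an estimated correlation). Among them the pyruvate kinase gene Pkm went from 843.1 ± 22.9 to 343.1 ± 21.4 RPKM (SD, n = 2, limma adjusted p = 1.58e-05), and the glucose transporter gene Slc2a1 fell by 1.07 on the log2 scale. Dntt, which encodes the terminal transferase that adds nucleotides at V(D)J joins, went from 177.3 ± 17.4 to 5.31 ± 1.66 RPKM (adjusted p = 0.000197). Foxo1, a regulator of the recombinase genes, fell by 1.88 on the log2 scale.

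Among the genes that rose in the same cells, Nrgn, a calmodulin-binding protein gene best known from neurons, went from 5.87 ± 4.06 to 616.4 ± 70.7 RPKM (SD, n = 2, adjusted p = 1.14e-06). Spp1 (osteopontin) rose by 4.38 and the LIM homeobox gene Lhx2 by 4.47 on the log2 scale. Of the pre-B and later B genes, 8 of 22 rose and 3 fell (12 called when adjusted over the list alone), without a call for the list (camera adjusted p = 0.0766, but 0.0393 after quantile normalization and 0.0313 after median-ratio scaling, and adjusted p = 0.696 with an estimated correlation). The inhibitory receptor gene Cd22 rose by 2.91, the MHC class II gene H2-Aa by 4.27 and Irf4 by 1.77, while the lymphotoxin gene Ltb went from 33.6 ± 0.17 to 0.423 ± 0.027 RPKM. B-lineage identity genes went both ways, with 9 of 24 up and 11 down (20 adjusted over the list alone; camera adjusted p = 0.619). Pre-BCR signalling genes were 3 up and 8 down of 21 (11 adjusted over the list alone; camera adjusted p = 0.0781), with the adaptor gene Blnk and the kinase gene Pik3cd down and Lyn up.

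Across all 11937 genes, 2791 were called in pro-B cells, 1610 up and 1181 down; the split was 1396 and 1315 after quantile normalization and 1314 and 1386 after median-ratio scaling. Leaving out control replicate 1 gave 1693, control replicate 2 gave 1688 and deleted replicate 2 gave 1846. Integrin and adhesion genes were 10 up and 8 down of 39, among them Icam1 (log2 -2.90) and Actn1 (log2 2.01). Stem and progenitor genes included a rise of Lmo2 (log2 3.08) and a fall of Erg (log2 -3.03), in 5 up and 2 down of 15. The cytokine-response genes Pim1 and Ccnd3 (log2 -1.75) fell, in an IL-7 and STAT5 list with 5 up and 4 down of 20. Of the other lists, Notch targets were 1 up and 3 down of 10, interferon-stimulated genes 5 up and 1 down of 22, immediate early genes 4 up and 3 down of 16, and chemokine receptor and migration genes 4 up and 5 down of 21. Markers of other cell types were mostly not called: myeloid genes were 3 up and 1 down of 22, T-lineage genes 2 up and 1 down of 11, erythroid genes 1 up and 1 down of 14, NK and dendritic genes 3 up of 10 and plasma cell genes 3 down of 9. Of 23 matched myeloid genes, 3 averaged at least 1 RPKM in the pro-B controls, so most had no room to fall. Among genes picked after their values were seen, Prtn3 was at 0.18 and 0.1 RPKM in the controls and 6.22 and 4.82 after deletion. In the same order, Csf1r was at 0.16 and 0.2 against 2.38 and 1.8, and Cebpa at 1.6 and 2.66 against 11.26 and 5.07. Lyz2 was lower after deletion, at 3.5 and 1.76 against 13.45 and 12.71. Mitotic genes had 1 up of 24, DNA replication genes 1 up and 2 down of 25, NuRD and PRC2 subunits 1 up and 2 down of 16 and the Ikaros family 2 up of 5. Without scaling, glycolysis was the only list called by camera in this comparison; median-ratio scaling also called the pre-B and later B list and DNA replication (camera adjusted p = 0.0359, against 0.165 after quantile normalization, and adjusted p = 0.8745 with an estimated correlation), and quantile normalization the former. Over the 20 lists, 139 memberships of 366 tested were called, and 141 when each was adjusted over the list alone.

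In c-Kit-high pro-B cells, an early pro-B fraction, the genes that rose with deletion included Cdh5, the gene of an adhesion molecule of endothelial junctions, from 0.336 ± 0.137 to 85.8 ± 26.5 RPKM (SD, n = 2, limma adjusted p = 3.88e-07). The collagen chaperone gene Serpinh1 rose by 6.12, Cd248 (endosialin, a pericyte antigen) by 5.95 and the calmodulin-binding gene Pcp4 by 6.60 on the log2 scale. Ckm, the muscle creatine kinase gene, was listed at 0 in both controls and averaged 28.4 ± 1.08 RPKM after deletion. The stem and progenitor antigen gene Cd34 rose from 2.20 ± 2.42 to 23.1 ± 0.761 RPKM (adjusted p = 0.000801).

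Among the genes that fell in the same cells, the B-lymphoid kinase gene Blk fell by 2.74 on the log2 scale. Jchain, which encodes the antibody joining chain, fell by 3.34. Tnfrsf8 was listed at 0 in both deleted libraries, against 5.73 ± 1.14 RPKM in the controls. Pre-BCR signalling genes were 2 up and 4 down of 21 (10 called when adjusted over the list alone; camera adjusted p = 0.202), with Blnk at log2 -0.88 and Pik3cd at log2 -0.89.

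The feedback genes of cytokine signalling Socs2 (log2 1.79) and Cish (log2 1.55) rose, within an IL-7 and STAT5 list of 4 up and 5 down of 20 (11 adjusted over the list alone). Pre-B and later B genes were 6 up and 1 down of 22, with Cd22 (log2 2.94), Cd74 (log2 2.57) and H2-Aa (log2 2.31) up. Integrin and adhesion genes were 10 up and 5 down of 39 (17 adjusted over the list alone), with Actn1 (log2 2.35) and Cttn (log2 2.44) up. Myeloid markers were 3 up of 22, including the receptor gene Csf1r from 0.85 ± 0.732 to 8.35 ± 1.86 RPKM and Cebpa (log2 1.55). B-lineage identity genes were 5 up and 6 down of 24, and stem and progenitor genes 5 up and 1 down of 15. Glycolysis, with 1 up and 1 down of 20, was not called (camera adjusted p = 0.973), and mitotic genes had 0 calls of 24 by limma. No list was called by camera here. Over the 20 lists, 96 of 366 memberships were called, and 110 when each was adjusted over the list alone. The remaining lists were the Ikaros family (2 up and 1 down of 5), NuRD and PRC2 subunits (2 down of 16), chemokine receptors (3 up and 7 down of 21), Notch targets (1 up and 2 down of 10), T-lineage (1 up of 11), erythroid (0 called of 14), NK and dendritic (4 up and 1 down of 10), plasma cell (2 up and 2 down of 9), DNA replication (2 up of 25), interferon-stimulated (2 up of 22) and immediate early genes (2 up and 3 down of 16).

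In all, 2049 genes were called in c-Kit-high cells, 1381 up and 668 down. The split was 1266 up and 1183 down after quantile normalization, and 1178 and 879 after median-ratio scaling. Without deleted replicate 1 the count was 1342, and without deleted replicate 2 it was 1322. Histone transcripts made up 0.557% of RPKM in control replicate 1 and 0.627% in deleted replicate 2, against 0.062% and 0.05% in the other 2 libraries. Granulocyte RNA was also higher in the same pair, with S100a9 at 204.9 and 90.1 RPKM against 29.1 and 24.4, and Ngp at 132.3 and 69.8 against 18.6 and 15.3, each control before deleted. Control replicate 1 and deleted replicate 2 also carry consecutive library numbers and values of 2 step sizes. Both pre-B libraries are the only others with values of 2 step sizes. The fit has no block, so any shared processing of these libraries was not modelled.

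Rag2-null pro-B cells cannot rearrange their receptor genes and stay at the pro-B stage, so deletion was compared there without later cells. Adhesion genes rose: 22 of 39 integrin and focal adhesion genes rose and 4 fell (27 called when adjusted over the list alone; camera adjusted p = 0.000113, but adjusted p = 0.162 with an estimated correlation). They include the actin crosslinker gene Actn1, from 10.6 ± 3.27 to 77.9 ± 5.27 RPKM (SD, n = 2, limma adjusted p = 3.07e-07), while Itgb2 fell by 1.72 on the log2 scale. Glycolysis genes fell, with 11 of 20 down and 1 up (13 adjusted over the list alone; camera adjusted p = 8.85e-07, and adjusted p = 0.197 with an estimated correlation). Aldoa went from 1035 ± 86.6 to 398.5 ± 24.1 RPKM (log2 -1.37, or -0.90 after quantile normalization) and Tpi1 fell by 1.39 on the log2 scale.

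Among other genes that rose in these cells, Serpinh1 went from 4.01 ± 0.899 to 690.7 ± 257.8 RPKM (adjusted p = 1.16e-06), Cdh5 rose by 6.01 and the TEA-domain factor gene Tead2 by 5.40 on the log2 scale. Prg3, an eosinophil granule protein gene, went from 3.93 ± 2.97 to 335.3 ± 0.234 RPKM. Cd34 rose from 0.0276 ± 0.021 to 29.9 ± 13.9 RPKM (adjusted p = 3.51e-05). Gldc, the glycine decarboxylase gene, went from 158.3 ± 12.2 to 4.01 ± 2.73 RPKM, and the lymphoid genes Ltb (log2 -4.41), Blk (log2 -3.51), Cxcr5 (log2 -3.39) and Lck (log2 -2.14) fell. Spib, a B-lineage Ets factor gene, fell by 2.08, and Tcf3, which encodes the E2A factors, by 0.90 on the log2 scale.

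Interferon-stimulated genes were 10 up of 22 with 0 down (10 adjusted over the list alone; camera adjusted p = 0.000795, and adjusted p = 0.69 with an estimated correlation), with Oas3 (log2 2.04) and Ifih1 (log2 1.25) among them; after quantile normalization 4 rose. DNA replication genes were 1 down of 25 (1 adjusted over the list alone; camera adjusted p = 0.00887, but 0.629 after quantile normalization, and adjusted p = 0.69 with an estimated correlation). Pre-BCR genes were 5 down of 21 (5 adjusted over the list alone; camera adjusted p = 0.0251, but 0.932 after quantile normalization, and adjusted p = 0.69 with an estimated correlation). Lists not called by camera were B-lineage identity (1 up and 4 down of 24), pre-B and later B genes (3 up and 3 down of 22), chemokine receptors (3 up and 5 down of 21, S1pr1 rising by 2.22 on the log2 scale), Notch targets (3 up and 2 down of 10, Notch1 rising by 1.42), stem and progenitor genes (5 up of 15; camera adjusted p = 0.0607, but 0.018 after quantile normalization and 0.013 after median-ratio scaling, and adjusted p = 0.69 with an estimated correlation), IL-7 and STAT5 targets (8 up and 5 down of 20), plasma cell genes (3 up and 1 down of 9, Xbp1 at log2 -1.06), T-lineage (1 up and 4 down of 11), myeloid (5 up of 22), erythroid (1 up and 1 down of 14), NK and dendritic (2 up of 10), mitotic (4 down of 24; camera adjusted p = 0.0607, but 0.0406 after median-ratio scaling and 0.629 after quantile normalization, and adjusted p = 0.69 with an estimated correlation), immediate early (6 up and 1 down of 16), NuRD and PRC2 (3 up and 2 down of 16) and the Ikaros family (1 up and 1 down of 5). Over the 20 lists, 132 of 366 memberships were called, and 143 when each was adjusted over the list alone. Of the stem and progenitor genes, 10 were called when adjusted over that list alone, 9 up and 1 down.

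In Rag2-null cells 2667 genes were called, 1850 up and 817 down. Quantile normalization gave 1161 up and 843 down with a shift of the median gene by -0.18 on the log2 scale, and median-ratio scaling 1452 up and 1419 down with a shift of -0.13. Without deleted replicate 1 the count was 1618, and without deleted replicate 2 it was 1577. Ribosomal protein genes took 11.88% and 12.97% of RPKM in the controls and 9.01% and 9.58% in the deleted libraries.

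Genes that changed the same way in all 3 deletions were counted next, since the settings share no libraries. There were 460 that rose and 175 that fell in all 3, against 28.9 and 4.52 for independent lists of those sizes. The 3 comparisons come from the same fit and share each gene's variance estimate. Genes of low spread can thus be called in several, so the numbers for independent lists understate overlap by chance. After quantile normalization the counts were 367 and 224. Rising genes included the neuronal and developmental genes Nrgn, Pcp4, Rasd2 and Pianp, the transcription factor genes Tbx19 and Tead2, and Nrp1, which encodes the semaphorin and VEGF co-receptor neuropilin. Nrp1 rose by 3.37 in pro-B, 3.81 in c-Kit-high and 3.83 in Rag2-null cells on the log2 scale, the last being 6.10 with a pseudocount of 0.1. Falling genes included Ltb, Blk, the NF-kB pathway adaptor gene Tifa and Bst1, the BP-3 antigen of early B-lineage cells. Bst1 had log2 values of -1.79, -1.79 and -3.13 in the same order, and Tifa -1.96, -2.01 and -1.86. Pearson's r of the log2 changes, across genes that are not independent replicates, was 0.57 for pro-B with c-Kit-high, 0.44 for pro-B with Rag2-null and 0.59 for c-Kit-high with Rag2-null. Of genes called in both, 51 of 1145, 211 of 1248 and 40 of 1031 had opposite directions, in the same order.

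**Figure D2:**
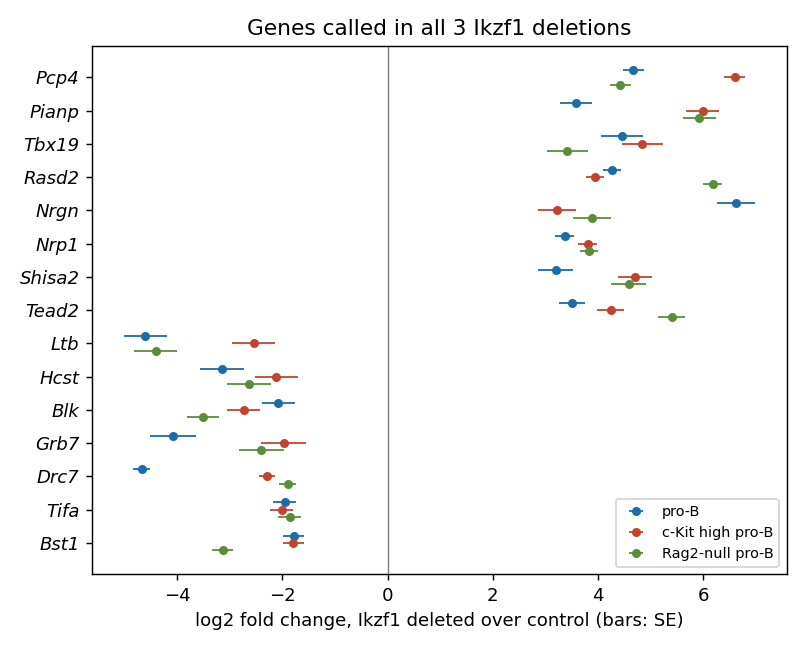
Log2 fold change (deleted over control, horizontal axis) of genes called the same way in all 3 deletions, with a dot for each of pro-B, c-Kit-high and Rag2-null cells and bars for the SE. Nrp1 lies at 3.37, 3.81 and 3.83 and Bst1 at -1.79, -1.79 and -3.13 in that order.

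Some effects differed between settings by a direct test of the difference. Gldc went from 66.7 to 0.436 RPKM in pro-B and 158.3 to 4.01 in Rag2-null cells, and was 0.018 and 0.409 in c-Kit-high cells, so its effect there was 5.98 higher on the log2 scale than in pro-B cells (limma adjusted p = 8.71e-05). Being near 0 in the c-Kit-high controls, Gldc could not fall there, so this difference does not show a weaker effect of deletion. The lipid desaturase gene Scd1 rose in c-Kit-high cells only among the 3, from 6.89 to 45.0 RPKM (difference from pro-B log2 2.55, adjusted p = 2.74e-05). Tox, a lymphoid HMG-box factor gene, went from 0.29 to 15.5 RPKM in pro-B cells, with a difference of -3.43 for c-Kit-high and -3.67 for Rag2-null cells. The fibronectin gene Fn1 went from 16.6 to 305.6 RPKM in Rag2-null and from 73.3 to 57.5 in pro-B cells (difference 4.48, adjusted p = 1.01e-05). The chemokine gene Ccl2 fell in pro-B cells, from 17.2 to 0.859 RPKM, and rose in Rag2-null cells, from 3.26 to 13.8 (difference 5.17). The T-lineage kinase gene Lck went from 44.1 to 9.23 RPKM in Rag2-null and from 34.8 to 51.9 in pro-B cells (difference -2.71).

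By count, 800 genes had a different effect in c-Kit-high and pro-B cells. That count was 384 and 518 without c-Kit-high deleted replicate 1 or 2, 462 and 327 without pro-B control replicate 1 or 2, 387 without pro-B deleted replicate 2 and 506 without c-Kit-high control replicate 2. Between Rag2-null and pro-B cells it was 1562, with 1028 and 918 without pro-B control replicate 1 or 2 and 944 without pro-B deleted replicate 2. Between Rag2-null and c-Kit-high cells it was 756, with 361 and 436 without c-Kit-high deleted replicate 1 or 2, and 448 and 438 without Rag2-null deleted replicate 1 or 2. Without both c-Kit-high libraries of high histone share it was 422.

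Wild-type pre-B libraries were compared with the c-Kit-high controls to describe the stage change; genotype differs along with stage. Pre-B and later B genes rose, 17 of 22 with 0 down (18 when adjusted over the list alone; camera adjusted p = 6.32e-11, and adjusted p = 0.0241 with an estimated correlation). Cd2 went from 1.41 ± 0.924 to 246.8 ± 3.69 RPKM (SD, n = 2, limma adjusted p = 1.08e-08), and Il2ra, the CD25 gene that marks small pre-B cells, rose by 5.60 and Spib by 3.23 on the log2 scale. Ikzf1 itself rose by 1.53 and its relative Ikzf3 by 4.00. The controls were Ikzf1(fl/+) with Cre and the pre-B cells wild-type, so the Ikzf1 value cannot be assigned to stage. The surrogate light chain genes fell: Igll1 went from 1867 ± 400.9 to 20.5 ± 2.87 RPKM, Vpreb1 had a log2 change of -6.26, and Vpreb2, whose reads may be shared with Vpreb1, of -6.40. Dntt fell by 7.34 and Kit by 3.30 on the log2 scale. Against total pro-B controls instead, the log2 change was 2.47 for Ikzf1 and -4.52 for Dntt.

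Cell division genes fell at this step: 24 of 24 mitotic genes (24 adjusted over the list alone; camera adjusted p = 2.75e-09, but adjusted p = 0.24 with an estimated correlation) and 25 of 25 DNA replication genes (25 adjusted over the list alone; camera adjusted p = 1.19e-11, and adjusted p = 0.188 with an estimated correlation). The log2 change was -2.15 for the DNA ligase gene Lig1, -1.60 for the cyclin gene Ccna2 and -3.24 for Myc. NuRD and PRC2 subunits were 9 down of 16 (9 adjusted over the list alone; camera adjusted p = 0.0117, and adjusted p = 0.224 with an estimated correlation), with Mta1 at log2 -1.86. Chemokine receptor genes were 14 up and 1 down of 21 (15 adjusted over the list alone; camera adjusted p = 1.13e-05, and adjusted p = 0.0965 with an estimated correlation), with the lymph node homing receptor gene Ccr7 at log2 2.66. Other lists had no camera call: the pre-BCR (8 up and 6 down of 21), B-lineage identity (12 up and 7 down of 24), integrins (13 up and 12 down of 39), IL-7 and STAT5 targets (5 up and 9 down of 20), stem and progenitor genes (2 up and 7 down of 15), Notch targets (2 up and 7 down of 10), T-lineage (4 up and 6 down of 11), plasma cell (4 up and 4 down of 9), glycolysis (4 up and 8 down of 20), interferon-stimulated (4 up and 10 down of 22), immediate early genes (8 up and 3 down of 16) and the Ikaros family (2 up of 5). Over the 20 lists, 278 of 366 memberships were called, and 287 when each was adjusted over the list alone.

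Markers of myeloid and red cells were also higher in the pre-B libraries. All 22 tested myeloid genes rose (22 adjusted over the list alone; camera adjusted p = 2.79e-13, but adjusted p = 0.175 with an estimated correlation). The granulocyte calprotectin gene S100a9 was at 2509 and 2569 RPKM in pre-B, 204.9 and 29.1 in the c-Kit-high controls, and listed at 0 in the pro-B and Rag2-null libraries. Its log2 change of 5.01 was 6.40 without control replicate 1 and 3.63 without control replicate 2, and its call was lost with the compared libraries alone in the fit. The neutrophil elastase gene Elane rose by 4.20 and Mpo by 4.00 on the log2 scale. Against total pro-B controls the log2 changes were 11.31 for S100a9, 7.75 for Elane and 7.94 for Mpo. Erythroid and megakaryocyte genes were 10 up of 14 (11 adjusted over the list alone; camera adjusted p = 3.63e-05, and adjusted p = 0.0241 with an estimated correlation), including the red cell membrane gene Slc4a1 from 0.946 ± 0.267 to 15.2 ± 1.41 RPKM. NK and dendritic cell genes were 7 up and 2 down of 10 (9 adjusted over the list alone; camera adjusted p = 0.00733, and adjusted p = 0.24 with an estimated correlation), including Tlr9 (log2 3.61). In all 5848 genes were called, 2289 up and 3559 down. Quantile normalization gave 2997 up and 2954 down with a shift of the median gene by 0.15, and median-ratio scaling 3088 and 2759 with a shift of 0.17.

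**Figure D3:**
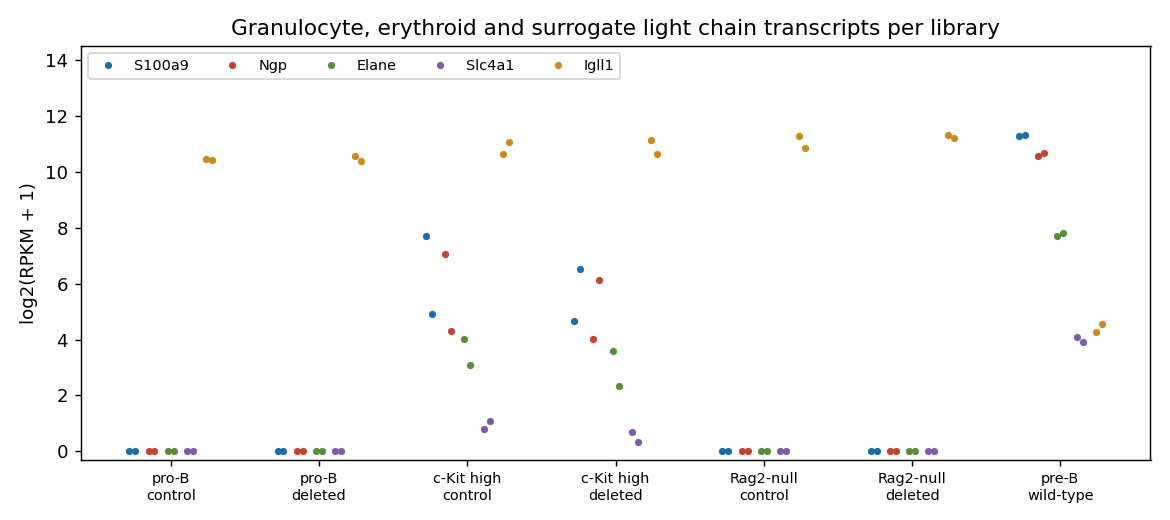
Log2(RPKM + 1) of the granulocyte genes S100a9, Ngp and Elane, the red cell gene Slc4a1 and the surrogate light chain gene Igll1 in the pro-B, c-Kit-high, Rag2-null and pre-B groups; dots are libraries. Igll1 averages 20.5 RPKM in pre-B, and S100a9 is listed at 0 in the pro-B and Rag2-null libraries.

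Whether deletion moves genes the way the stage change does was asked by correlating log2 changes. The myeloid and erythroid genes that were higher in the pre-B libraries, whose source is open, enter these correlations and counts. A correlation without them was not computed. For the Rag2-null deletion, which shares no library with the stage comparison, Pearson's r was -0.0213 and Spearman's rho 0.0383 across 11937 genes, which are not independent replicates. Without Rag2-null control replicate 2, r was 0.0136, and without control replicate 1 it was -0.0524. With the pro-B deletion in its place r was 0.200. Of 1610 genes that rose in pro-B cells, 558 rose in pre-B, against 308.7 for independent lists, and 576 of 1181 that fell also fell, against 352.1, while 359 rose with deletion and fell in pre-B, against 480.0, and 161 fell with deletion and rose in pre-B, against 226.5. For the Rag2-null deletion 380 rose in both, against 354.7, 346 fell in both, against 243.6, 607 rose with deletion and fell in pre-B, against 551.6, and 172 fell with deletion and rose in pre-B, against 156.7. All of these Rag2-null counts exceed those for independent lists. The deletion and stage comparisons share each gene's variance estimate, so an excess alone does not show agreement. H2-Aa and Cd22 (log2 3.11 and 1.97 in pre-B) rose with the pro-B deletion and in pre-B, and Dntt and Erg (log2 -4.59 in pre-B) fell in both.

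In cultured pre-pro-B cells, knock-down of Ikzf1 raised myeloid genes. Of 14 tested myeloid markers 10 rose and 1 fell (11 and 2 with the run as a block; 12 when adjusted over the list alone; camera adjusted p = 5.22e-09, but adjusted p = 0.063 with an estimated correlation). The list holds 23 genes, and the rest were too low to be tested. Elane, Cd14 and Ltf reached 1 RPKM only in hairpin libraries, so they entered the test through their rise. Among the controls Csf1r reached it only in Ren713 replicate 1, at 1.24 RPKM, so Csf1r too passed the filter through the hairpin libraries. Outside the naming rule, Fcer1g did not rise, at 236.1 to 351.2 RPKM in the controls and 218.1 to 302.7 with the hairpins. Tyrobp, also outside it, did not rise either. The proteinase 3 gene Prtn3 went from 15.8 ± 8.13 to 763.7 ± 248.5 RPKM (SD, n = 8 each, limma adjusted p = 9.85e-09). The macrophage growth factor receptor gene Csf1r went from 0.522 ± 0.371 to 20.4 ± 7.64 RPKM, and Ly6c2, a monocyte antigen gene, rose by 4.31. The cathepsin G gene Ctsg rose by 3.26, the mannose receptor gene Mrc1 by 3.55 and Cd68 by 2.56 on the log2 scale. The 10 myeloid markers that rose were higher in each of the 4 runs, and the log2 change of Prtn3 was 5.36, 5.52, 5.35 and 6.27 in runs 1 to 4.

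Among the genes that fell in the knock-down cells, Jchain went from 41.9 ± 11.3 to 10.5 ± 4.61 RPKM (adjusted p = 2.84e-08), Mzb1, a chaperone gene of marginal zone B cells, fell by 1.86, the cathepsin W gene Ctsw of cytotoxic lymphocytes by 1.91 and Cd24a by 1.67 on the log2 scale. Pre-BCR genes rose from low levels, 7 of 16 with 0 down (9 up and 1 down with the block; 7 adjusted over the list alone; camera adjusted p = 0.000762, but adjusted p = 0.448 with an estimated correlation). Igll1 went from 0.607 ± 0.177 to 12.8 ± 11.4 RPKM, Vpreb2, whose reads may be shared with Vpreb1, from 0.131 ± 0.0871 to 4.39 ± 4.22, and Cd79b rose by 1.53 on the log2 scale. At these control levels Igll1 and Vpreb2 entered the test through their rise and had little room to fall. B-lineage identity genes were 6 up and 7 down of 16 (7 and 8 with the block). Integrin and adhesion genes were 16 up and 2 down of 35 (25 and 4 with the block; 21 adjusted over the list alone; camera adjusted p = 0.0003, and adjusted p = 0.401 with an estimated correlation), with Actn1 (log2 1.44) and Itga5 (log2 0.83) up.

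Subunits of the NuRD and PRC2 complexes, partners of Ikaros, were 4 down of 16 (14 down with the block; 4 adjusted over the list alone; camera adjusted p = 0.000121, and adjusted p = 0.378 with an estimated correlation), led by Mta3 from 61.3 ± 2.73 to 39.8 ± 3.33 RPKM (adjusted p = 1.91e-06). DNA replication genes were 6 down of 25 (1 up and 16 down with the block; 9 adjusted over the list alone; camera adjusted p = 9.43e-05, and adjusted p = 0.378 with an estimated correlation), with Ccne1 at log2 -0.47. Immediate early genes were 6 up of 17 (9 up and 1 down with the block; 9 adjusted over the list alone; camera adjusted p = 0.0213, and adjusted p = 0.639 with an estimated correlation), with Ier3 and Jun up. Erythroid and megakaryocyte genes were 3 up and 1 down of 5 (3 and 1 with the block; 4 adjusted over the list alone; camera adjusted p = 0.0415, but 0.131 with the run as a block and 0.0609 after quantile normalization, and adjusted p = 0.378 with an estimated correlation), with the platelet gene Gp9 at log2 1.67. Mitotic genes were 1 down of 24 (8 down with the block, and 0 called when adjusted over the list alone). The camera adjusted p of that list was 0.109, or 0.0488 with the run as a block, and 0.713 with an estimated correlation and no block. Not called by camera were stem and progenitor genes (4 up and 2 down of 12, Cd34 rising by 0.90 and Meis1 falling by 1.13 on the log2 scale), IL-7 and STAT5 targets (4 up and 4 down of 19, Ccnd2 rising by 1.48), chemokine receptors (4 up and 3 down of 22, Cxcr3 rising by 2.37), T-lineage (3 up and 5 down of 11, Thy1 at log2 -1.13), pre-B and later B genes (5 up and 4 down of 14), NK and dendritic (5 up and 3 down of 13), plasma cell (2 up and 3 down of 7), interferon-stimulated (5 up of 14; camera adjusted p = 0.0738, but 0.0422 after median-ratio scaling and 0.177 after quantile normalization, and adjusted p = 0.713 with an estimated correlation), Notch targets (1 up and 2 down of 10), glycolysis (1 up of 19) and the Ikaros family (1 down of 3). With the block, the members up and down in these lists were 5 and 5 for stem and progenitor genes, 7 and 7 for IL-7 and STAT5 targets, 6 and 6 for chemokine receptors, 3 and 6 for T-lineage, 5 and 5 for pre-B and later B genes, 5 and 5 for NK and dendritic, 3 and 4 for plasma cell, 7 and 1 for interferon-stimulated, 1 and 3 for Notch targets, 3 and 6 for glycolysis and 0 and 1 for the Ikaros family. Over the 20 lists, 131 of 312 memberships were called, and 144 when each was adjusted over the list alone.

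**Figure D4:**
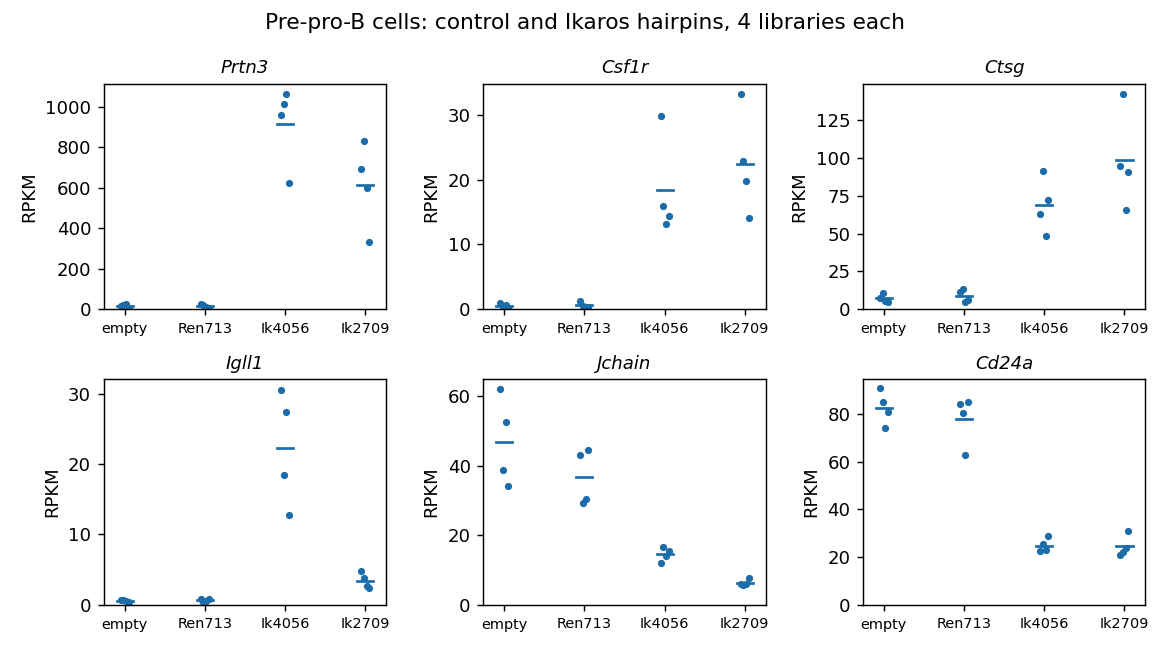
RPKM of Prtn3, Csf1r, Ctsg, Igll1, Jchain and Cd24a, on a separate linear axis each, in the pre-pro-B libraries of the 4 constructs; dots are libraries and bars group means. Prtn3 averages 914.7 RPKM with Ik4056 and 612.8 with Ik2709, against 15.6 with Ren713.

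By count, 2086 genes were called with the knock-down, 1437 up and 649 down, and 5575 (3095 up and 2480 down) with the run as a block. Quantile normalization without the block gave 1242 up and 1124 down, and median-ratio scaling 1294 and 977. Of the genes tested in this fit and in the pro-B fit, 557 rose with the knock-down and in the Rag2-null deletion, against 195.3 for independent lists, and 99 fell in both, against 41.1 (r = 0.43 of the log2 changes across genes). The same counts were 418 against 136.2 and 74 against 29.6 for the c-Kit-high deletion (r = 0.313), and 402 against 177.6 and 125 against 51.8 for the pro-B deletion (r = 0.196). Actn1 and Cd34 rose with the knock-down and in the Rag2-null deletion.

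The hairpins were also compared singly. Against Ren713, Ik4056 called 1566 genes (1194 up and 372 down; 4973 with the block; 927 and 728 after quantile normalization) and Ik2709 called 962 (683 up and 279 down; 3457 with the block; 600 and 388 after quantile normalization). By limma 0 genes differed between Ren713 and the empty vector, with 58 at an unadjusted p under 0.05, and 9 were called with the block. The smallest p values there were for Pcyox1l (log2 -0.71, adjusted p of 1 without the block and 0.000193 with it) and Rnf11 (log2 -0.41, 0.0455 with it). With controls split between them, Pearson's r of their log2 changes across genes was 0.779, and 0.821 with the shared Ren713 control, where unchanged groups simulated against that control gave 0.498. The covariance was 0.141 against a simulated 0.0226.

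Ik4056 and Ik2709 were then tested against each other. The LIM-only gene Lmo4 was higher with Ik4056, at 148.7 ± 14.47 against 57.3 ± 2.68 RPKM (SD, n = 4, limma adjusted p = 1.89e-06), as was Vpreb2 (log2 2.14), while the nuclear lamina gene Lmna (log2 -1.41), the actin regulator gene Wdr1 (log2 -1.17) and Cmtm6 (log2 -1.29) were lower. Genes chosen after their values were seen were Igll1, at 22.3 ± 8.17 against 3.40 ± 1.14 RPKM (adjusted p = 3.67e-05), and Ikzf1 itself, at 39.9 ± 14.7 against 46.0 ± 12.97 (adjusted p = 0.948). In all 358 genes differed, 282 higher and 76 lower with Ik4056 (2407 with the block; 229 and 137 after quantile normalization), and 230 without Ik4056 replicate 1.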

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

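The test of mature granulocytes in the knock-down cultures and the counts with no filter were chosen after the result was seen, and the fits without a whole library run or without both c-Kit-high libraries of high histone share were added after seeing the data; the other tests of this part were planned before their results were seen.

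The first pattern is the level of myeloid genes in the pre-B libraries, where all 22 tested markers were higher than in the c-Kit-high controls. The shallow c-Kit-high control library of 2.3 M reads is argued against, since without it 100% of the 22 were still called higher. RNA from granulocytes in the pre-B samples is a candidate source: of a second list of granulocyte genes, with no member of the first, 20 of 23 tested were called higher, or 86.96%, and 14 of 24 matched already average at least 1 RPKM in the c-Kit-high controls, against 5 in the total pro-B controls. Their abundant transcripts were there, with S100a9 at 2509 and 2569 RPKM, Ngp at 1510 and 1634 and Elane at 206.1 and 222.8, and no sort or gate that would remove granulocytes is named for these cells. Whether cells of the B lineage hold part of this RNA stays open, and the wild-type genotype, which goes with the stage here, was not tested. Both pre-B libraries and c-Kit-high control replicate 1 held values of 2 step sizes, unlike control replicate 2. Whether shared processing adds to the myeloid signal was not tested.

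For the second pattern, the rise of myeloid genes with the Ikzf1 knock-down in pre-pro-B cells, an effect of a single hairpin is argued against. Of the 10 myeloid markers that rose, 100% were called higher with each hairpin against the shared Ren713 libraries. These 10 were picked by their rise with both hairpins together in the same libraries, so neither comparison is independent of that choice. Mature granulocytes in the cultures are argued against, since 25.0% of 24 matched genes of the second granulocyte list were called higher (6 up of 9 tested), or 20.83% with no filter on low values, and S100a9 was listed at 0 in all 16 libraries. A contribution of monocytes and macrophages cannot be told apart from a change in the cultured cells: 27.59% of 29 matched genes of a second list were called higher (8 up and 1 down of 12 tested), but 51.72% with no filter, so that the filter sets on which side of the 50% bound the value falls. In the control-vector libraries 10 of the 29 and 5 of the 24 already average at least 1 RPKM. Early granulocyte precursors stay open: Prtn3 was at 331.4 to 1061 RPKM and Elane at 0.96 to 4.27 with the hairpins, whereas the pre-B libraries held 116.0 and 123.4 of Prtn3 beside their Elane levels. Whether the pre-pro-B cells themselves turn on Prtn3, Csf1r and Mpo when Ikaros is lowered was not tested.

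The third pattern is the higher level of the surrogate light chain genes Igll1 and Vpreb2 with Ik4056 than with Ik2709. Igll1 was higher with Ik4056 in each run, by 2.43, 2.02, 2.97 and 2.03 on the log2 scale, while Ikzf1 differed by 0.04, -0.37, -0.37 and -0.23. A weaker knock-down with Ik2709 and a difference between the hairpins in other targets cannot be told apart: of 253 genes called with the knock-down and between the hairpins, 86.17% had the larger change with Ik4056, between the bounds of 90% and 60% set for either reading. RNA levels of Ikzf1 do not give the protein, which was not measured in these libraries. Reads shared between Vpreb1 and Vpreb2 were not tested and do not enter the Igll1 values.

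Deletion effects differed between settings by a test of the difference itself. Between c-Kit-high and pro-B cells 800 genes differed, among them Cd248 (log2 3.67), Scd1 (2.55), Gldc (5.98), Tox (-3.43) and the homeobox gene Emx2 (-3.99), whose call was lost with a pseudocount of 0.1. Gldc was barely detected in the c-Kit-high controls and could not fall there. Between Rag2-null and pro-B cells 1562 genes differed, among them Fn1 (4.48), Ccl2 (5.17), the cyclin gene Ccnd1 (2.66), Lck (-2.71), the proton channel gene Hvcn1 (-4.08) and Tox (-3.67). Between Rag2-null and c-Kit-high cells 756 genes differed, among them the metalloproteinase gene Mmp15 (4.65), Rasd2 (2.24, lost with a pseudocount of 0.1), Scd1 (-2.49), Lck (-2.32) and Cd248 (-3.13). Cd248 itself rose in all 3 settings, from 43.4 to 216.4 RPKM in pro-B, 1.45 to 151.0 in c-Kit-high and 28.8 to 210.3 in Rag2-null cells. Hvcn1 went from 6.47 to 108.8 RPKM in pro-B and was 4.73 and 3.97 in Rag2-null cells.

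Single libraries stood apart from the other 3 of their group for 6 values among the knock-down libraries. Csf1r was at 29.9 RPKM in Ik4056 replicate 1 (others 13.2 to 16.0), Jun at 20.4 in Ik2709 replicate 4 (others 10.6 to 11.2) and Vpreb2 at 1.36 in Ik2709 replicate 2 (others 0.734 to 0.835). Cd68 was at 6.19 in empty-vector replicate 4 (others 3.37 to 3.81), F13a1 at 1.51 in Ren713 replicate 1 (others 0.643 to 0.737) and Cdc6 at 20.7 in the same library (others 19.0 to 19.3). These are 6 of 208 groups of 4 examined, or 2.9%, where chance alone gives about 1 in 20.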

How the results depend on the processing

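The fits without a library run, without both c-Kit-high libraries of high histone share, and of hairpin agreement without a replicate were chosen after seeing the data. Of 245 gene results followed, 218 kept their direction and side of the threshold under all alternatives run, 19 lost the call under at least 1, 6 gained it and 2 reversed. Calls lost without a single replicate were those of Ikzf1, Ezh2, Mta3 and Grb7 in c-Kit-high cells and of Ikzf1 and Pax5 in Rag2-null cells. Those 2 were not called: Rag1 in Rag2-null cells ranged from -1.06 to 0.31 (log2) without a replicate, with 0.31 without control replicate 1 and 0.17 without deleted replicate 2, and Ikzf3 there from -1.86 to 0.98, with 0.54 without control replicate 2 and 0.98 without deleted replicate 1. A 2-fold minimum left 1143 genes in pro-B, 914 in c-Kit-high and 996 in Rag2-null cells, 2603 in pre-B and 336 in the knock-down; it removes small changes by construction. Fits on the compared libraries alone called 1350 genes in c-Kit-high and 1547 in Rag2-null cells, but 3222 in pro-B cells; the cause was not tested. Without both high-histone libraries 422 genes differed between the Rag2-null and c-Kit-high effects. With the run as a replicate block the counts were 5575 for the knock-down, 4973 for Ik4056, 3457 for Ik2709, 9 for Ren713 against empty vector and 2407 between hairpins. The block also called Pcyox1l and Rnf11 and the mitotic list, lost the erythroid list, and changed no other named gene or list call. The mitotic list had a camera adjusted p of 0.713 with an estimated correlation and no block. With fewer libraries, leaving out run 1 gave 1340 genes for the knock-down, 980 for Ik4056, 536 for Ik2709 and 139 between hairpins; run 2 gave 937, 542 and 125 for the last 3, and run 3 gave 548 for Ik2709 and 203 between hairpins. Without run 4, 3 genes differed between Ren713 and empty vector. The correlation of deletion and stage was -0.045 after quantile normalization, 0.2004 with the pro-B deletion and 0.0304 with total pro-B controls; the cause was not tested. List calls numbered 2 with an estimated correlation and 40 with fry, which tests another question, against 21. Without a replicate the ranges were 1688 to 1915 (pro-B), 1322 to 2117 (c-Kit-high), 1577 to 2509 (Rag2-null), 327 to 1036, 918 to 1533 and 361 to 1038 (c-Kit-high against pro-B, Rag2-null against pro-B, Rag2-null against c-Kit-high), 0 to 1 (Ren713), 230 to 369 (between hairpins), -0.0524 to 0.0136 (stage) and 0.7203 to 0.7998 (hairpin agreement). A group left with 1 library is assumed to vary like the others. Low depth, 2.3 M reads in a c-Kit-high control, limits low genes there.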

Other observations

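Genes of this part outside the naming rule, and the splits that part every run, were chosen after the result was seen; the other splits were planned. The recombinase genes Rag1 and Rag2, which start antigen receptor rearrangement, were examined by setting. In pro-B cells Rag1 went from 17.5 ± 3.79 to 0.536 ± 0.476 RPKM (SD, n = 2, limma adjusted p = 0.000988) and Rag2 from 5.27 ± 1.23 to 0.025 ± 0.0016 (adjusted p = 4.69e-05). In c-Kit-high cells Rag2 went from 54.7 ± 20.1 to 15.2 ± 2.94 RPKM (adjusted p = 0.00128), while Rag1, at 322.2 ± 55.3 and 112.0 ± 44.2, was not called (adjusted p = 0.0706). That call was gained after quantile normalization, by limma without trend and robust moderation, with all 30 libraries in a single fit and with the compared libraries alone. In Rag2-null cells Rag1 was at 30.1 and 11.1 RPKM in the controls and 20.8 and 9.20 in the deleted libraries (adjusted p = 0.686).

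Ikzf3 encodes Aiolos, the Ikaros relative of later B cells. It averaged 15.3 RPKM in pro-B controls and 70.2 ± 8.62 in deleted cells (adjusted p = 0.144), and 14 ± 5.68 and 77.1 ± 10.4 in c-Kit-high cells (adjusted p = 0.118). It was called in both settings with all 30 libraries in a single fit and with the compared libraries alone. In Rag2-null cells 1 library of each group was low, at 4.91 and 22.01 RPKM in the controls and 2.21 and 21.99 after deletion. That spread enters the test of this gene in every setting. The low library was replicate 1 in each group, and Rag1 was higher in replicate 1 of each. Whether replicate numbers pair the Rag2-null libraries was not tested, and the fit does not pair them.

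Other splits of the libraries were fitted to see whether chance can be excluded. For the knock-down, 2 of 100 splits, the real one among them, called at least the real 2086 genes, a share under 0.05. These splits disregard the runs, whose libraries are not interchangeable, so no conclusion on chance is drawn from this share. The highest other split called 4133; it puts 3, 1, 0 and 4 libraries of runs 1 to 4 on one side, so it follows the runs and points to a structure of the samples by run. With the run as a block and 2 libraries of each run on each side, 1 of 100 splits, the real one with 5575, called as many, and the highest other called 903. Chance is excluded among those splits, which keep the runs balanced. For Ik4056 against Ren713, 1 of 35 splits called the real 1566 (highest other 1). For Ik2709 against Ren713, 1 of 35 called the real 962 (highest other 0). These splits also disregard the runs, so no conclusion on chance is drawn from either share. For Ren713 against empty vector the real count of 0 is met by 35 of 35 splits whatever they call (highest other 0), so this test decides nothing. Between Ik4056 and Ik2709, 2 of 35 splits called at least the real 358, so chance is not excluded without the block. The highest other, with 465, parts runs 1 and 4 from runs 2 and 3.

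Among the 8 splits that part the libraries of every run, fitted with the block, the real one called 4973 genes for Ik4056 against a highest other of 0, 3457 for Ik2709 against 0, 9 for Ren713 against empty vector against 1, and 2407 between Ik4056 and Ik2709 against 1. The splits without this restriction differ in that they leave run differences inside the comparison. With 8 splits a share under 0.05 cannot be reached.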
